A study of Mus musculus with 18 samples.

How the data were processed

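The series holds 18 chromatin immunoprecipitation (ChIP-seq) and input libraries from mouse cells, 8 from normal CD4+ CD8+ double-positive (DP) thymocytes and 10 from T cell acute lymphoblastic leukaemia (T-ALL) driven by overexpression of Notch1-IC, the intracellular form of Notch1. For each of 3 histone marks (H3K27me3, H3K4me3 and H3K9ac) and for the micrococcal nuclease-treated input, each cell type has 2 libraries. T-ALL also has 1 Notch1 library and 1 sonicated input. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 min. Chromatin for the histone marks was cut to mononucleosomes with micrococcal nuclease and chromatin for Notch1 was sonicated. Libraries were made from 5 to 10 ng of DNA and sequenced as single-end reads of 36 bp, of which 34 bp remained after processing.

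The submitters' processing notes name the aligner BWA and the genome builds NCBIM37 and mm9, and its version and settings are not given in the sources used here. The tool that called regions and peaks, its thresholds, the use of the inputs and the way replicates were combined are not given in the sources used here. The authors deposited 4 region lists: 1 for each histone mark, described per the file headers as a comparison of Notch1-IC tumours with DP cells, and 1 of Notch1 peaks in T-ALL. Each list gives a chromosome, start and end. The deposited BED score is 1000 in every row of every list and so carries no measurement. All starts and all widths are multiples of 25 bp. In the histone lists each region has 1 of 2 display colours, green (RGB 0,200,0) or red (200,0,0), and no header says which colour is higher in T-ALL. The regions are therefore reported as green and red, and no fold change, significance value or depth per region was used. The lists carry no values per library, so the sequencing depth behind them is unknown, no spread between replicates could be computed, and no test between samples was made. The planned fits per replicate were not made for that reason.

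The gene table at hand is on another build (GRCm38), so no region was assigned to a gene, promoter, exon or intron. The planned counts of promoter genes, the 19 gene lists and the motif search were not run. Coordinates are mm9 as in the lists, converted to 1-based starts. As fixed before the data were examined for the case of no matching annotation, the regions named are the 10 widest of each list. Width takes the place of a value, since the lists carry none. Clusters of regions within 5 kb of each other were described after their values were seen.

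Regions of one list sharing 1 bp or more with another list were counted on the chromosomes present in both. The count was compared with 1000 circular shifts of the first list, each chromosome shifted by its own random offset over the span covered by the lists. The plan named upper and lower 1-sided values. The smaller of these was doubled to a two-sided p, whose smallest possible value is 0.002, and adjusted by the Benjamini-Hochberg method over the 12 pairs of histone lists or the 6 Notch1 overlaps. Shifts keep the spacing within a list but not the tendency of all lists to crowd into the same parts of a chromosome, so a second set of shifts, by 10 to 100 kb in either direction, was added after seeing the data. The shares of green and red regions holding a Notch1 peak, and the colours of 2 marks at shared regions, were compared by Fisher's exact test with Woolf 95% intervals of the odds ratio, adjusted over the 3 marks or pairs of marks. The plan had named these tests for promoters, and regions took the place of promoters once the lists had been seen. Regions are not independent replicates, so each of these tests was repeated, after seeing the data, by rotating the colours along each chromosome (1000 rotations, smallest p 0.001). The comparison of the sex chromosomes with the autosomes by Fisher's exact test, adjusted over its 3 tests, was chosen after its values were seen and was not repeated by rotation. Shares carry 95% Clopper-Pearson intervals, which cover counting error only. Alternatives tried were regions at or above the median width of each list, merging regions within 1 kb, autosomes only, requiring 50% of a region to be covered, Notch1 peaks at or above their median width, regions 500 to 1000 bp wide, the 11 chromosomes of the H3K9ac list, and counting clusters once.

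The shift test was checked on simulated lists with the sizes, widths and chromosome spans of the real ones. Regions were placed at random along each chromosome, so neither the clustering within lists nor the crowding of lists together was simulated. The calls with none moved therefore do not give the rate of false calls in the real lists. For each of the 6 Notch1 overlaps and for red H3K27me3 against red H3K4me3, 10 pairs of lists were simulated and tested with 200 shifts each. With 5% of the first list moved onto the second, the permutation test called all 10 pairs in every comparison at p = 0.05. The moved regions overlap by construction and are many more than the shifts give, so this checks the counting and says nothing of the power to detect small excesses. With none moved, it called 2 of 10 pairs for Notch1 against green H3K4me3, 1 of 10 for Notch1 against green H3K27me3 and for red H3K27me3 against red H3K4me3, and 0 of 10 for the others. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.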

Results

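The 3 histone comparisons asked where chromatin marks differ between normal DP thymocytes and Notch1-IC-driven T-ALL. H3K4me3 and H3K9ac are marks of active promoters and regulatory elements, and H3K27me3 is the repressive mark laid down by Polycomb repressive complex 2. Each comparison rests on 2 DP and 2 T-ALL libraries, and the Notch1 peak list on 1 T-ALL library. The deposited lists hold 22682 H3K27me3 regions, 21402 H3K4me3 regions, 1878 H3K9ac regions and 14569 Notch1 peaks. Every histone region is shown in green or red, and the sources used here do not say which colour is higher in T-ALL. No region carries a fold change, a significance value or a depth, so the size of a change and its spread between replicates cannot be given.

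H3K27me3 had the most listed regions, and its red regions outnumbered its green ones. There were 13012 red and 9670 green regions, so that green made up 42.6% (95% Clopper-Pearson interval 42.0 to 43.3). Red regions covered 11.7 Mb with a median width of 750 bp, and green regions covered 7.18 Mb with a median width of 650 bp. The green regions were packed more densely. In that class 66 clusters, built from regions within 5 kb of each other, held 10 or more regions, against 39 clusters of red regions.

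The largest green H3K27me3 cluster lay on chromosome 15 from 102771626 to 102840550 and held 33 green regions. It was followed on the same chromosome by clusters of 28 and 30 green regions, and the whole stretch from 102771626 to 102980775 held 91 green and 26 red H3K27me3 regions, 3 Notch1 peaks and 0 H3K4me3 regions of either colour. Further large green clusters lay on chromosome 11 from 96022476 to 96083075 (30 regions), on chromosome 3 from 87996251 to 88042575 (25 regions), on chromosome 2 from 74482001 to 74538125 (24 regions) and on chromosome 19 from 45344076 to 45391450 (24 regions). The remaining 3 of the 10 largest held 22 green regions each, on chromosome 6 from 52234676 to 52286725, on chromosome 9 from 91258326 to 91302325 and on chromosome 11 from 96098876 to 96137575. The chromosome 2 cluster also held 17 red H3K27me3 regions and 6 Notch1 peaks. The largest red H3K27me3 cluster lay on chromosome 12 from 112638876 to 112694925 and held 18 red regions and 0 green ones.

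**Figure D1:**
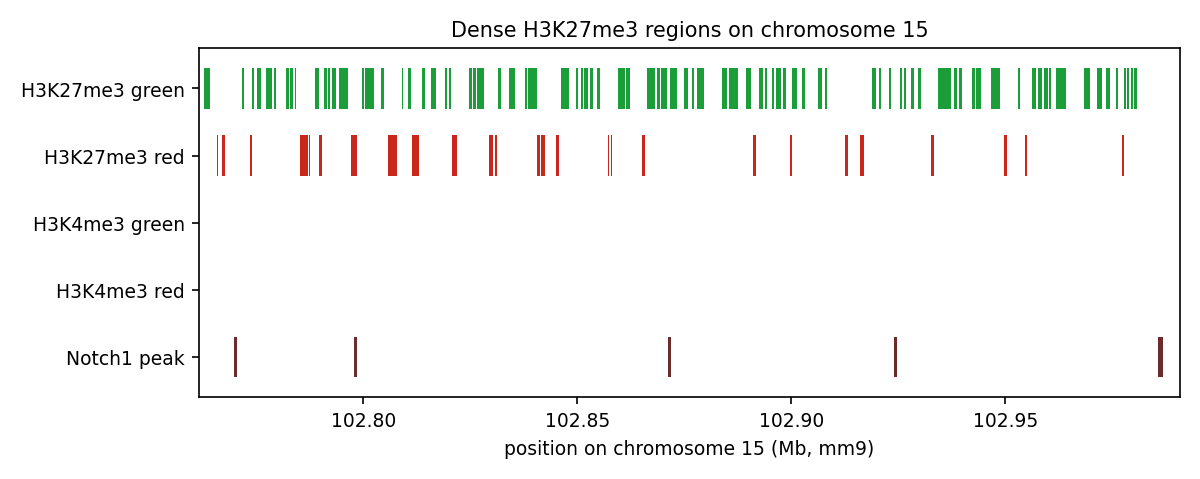
Map of the H3K27me3, H3K4me3 and Notch1 regions around the 3 large green H3K27me3 clusters of chromosome 15 (x axis, position in Mb on mm9; each row is 1 list and each box 1 listed region drawn to scale). Between 102771626 and 102980775 the 91 green H3K27me3 regions outnumber the 26 red ones, and the H3K4me3 rows are empty.

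Among single H3K27me3 regions the broadest red one was 5800 bp wide, on chromosome 5 from 111845576 to 111851375, and held 2 Notch1 peaks and 1 red H3K4me3 region. The broadest green one was 4500 bp wide, on chromosome 14 from 63879126 to 63883625, and shared no base with any other list. Of the 10 broadest red regions, 6 held a Notch1 peak and 5 a red H3K4me3 region. Of the 10 broadest green regions, 0 shared bases with another list.

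H3K4me3 regions were nearly balanced between the colours, and the broadest were green. There were 11160 red and 10242 green regions, a green share of 47.9% (47.2 to 48.5). The 10 broadest green regions were 5075 to 6675 bp wide, and 5 of them held green H3K9ac regions. The broadest lay on chromosome 2 from 11563526 to 11570200 and held 3 green H3K9ac regions. Another lay on chromosome 2 from 26369301 to 26374800, with 2 green H3K9ac regions, at the end of a cluster of 9 green H3K4me3 regions that began at 26350051. The 10 broadest red regions were 2525 to 5300 bp wide, and 8 of them shared bases with a red H3K27me3 region.

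The H3K9ac list was about evenly split between the colours and held regions on 11 chromosomes (1, 2, 3, 4, 6, 7, 9, 11, 16, 17 and 19). The list held 952 green and 926 red regions, a green share of 50.7% (48.4 to 53.0). The other chromosomes held none, although chromosome 5 held 692 green and 850 red H3K4me3 regions. Chromosome 7, of like span, held 87 green and 140 red H3K9ac regions. Whole autosomes without a region argue that the list does not cover them, although no source used here states this. The size of the list is therefore not a measure of how much H3K9ac differed, and those chromosomes were not analysed here for this mark. The broadest green H3K9ac region, 3125 bp wide on chromosome 3 from 106287326 to 106290450, lay inside a green H3K4me3 region 5725 bp wide. All 10 broadest green H3K9ac regions shared bases with green H3K4me3 regions. Of the 10 broadest red H3K9ac regions, 4 shared bases with green and 3 with red H3K4me3 regions. The largest green H3K9ac cluster held 8 regions on chromosome 6 from 41496401 to 41508525.

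Comparing marks at the same places, red H3K27me3 regions coincided with red H3K4me3 regions far more often than other pairs of these marks. Of 13012 red H3K27me3 regions, 1484 (11.4%) shared bases with a red H3K4me3 region, against a mean of 100.4 over circular shifts, a 14.8-fold excess (two-sided circular-shift permutation test, p = 0.002, the smallest the shifts can give, adjusted p = 0.003). The excess was 5.03-fold over local shifts and 24.5-fold with 50% of a region covered. Green H3K27me3 regions met green H3K4me3 regions 66 times, within the central 95% of the shifts (46 to 86), and met red H3K4me3 regions 160 times, 2.38-fold over the shifts and 4.12-fold among regions at or above the median width. Red H3K27me3 regions met green H3K4me3 regions 189 times, 2.03-fold over the shifts. These last 2 excesses were 1.04-fold and 1.17-fold over local shifts, and 1.10-fold and 1.26-fold with 50% of a region covered, and passed in neither. Over local shifts green with green was below chance, at 0.62-fold. Each cell type had 2 micrococcal nuclease-treated inputs, not divided by mark, and how the comparisons used them is not given. Part of the excess may come from shared inputs, which was not tested.

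Where a region of H3K27me3 met H3K4me3 of 1 colour, both marks had the same colour in 1523 of 1845 cases (82.5%). Nearly all of these were red in both marks (1460), and 63 were green in both. Green H3K27me3 regions met red H3K4me3 more often (157) than green, and 165 red ones met green. The percentage thus mostly reflects the 1460 meetings of red with red. Red was less dominant in the full lists, where green made up 42.6% of H3K27me3 and 47.9% of H3K4me3 regions. The odds ratio for sharing the colour was 3.55 (2.54 to 4.96; Fisher's exact test, adjusted p = 9.99e-12; rotation permutation p = 0.001). Among regions at or above the median width it was 1.59 and did not pass, while it was 5.43 among regions of 500 to 1000 bp and 22.1 with 50% of a region covered.

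H3K4me3 regions met H3K9ac regions far more often than the shifts gave, and no association of their colours was detected. The shares below are of H3K4me3 regions and are kept small by the short H3K9ac list (952 green and 926 red regions). The share of H3K9ac regions that met H3K4me3 was not computed. On the 11 shared chromosomes 469 green H3K4me3 regions (7.19%) met green H3K9ac regions, 72.3-fold over circular shifts, and 392 (6.01%) met red ones, 57.4-fold. Of red H3K4me3 regions 286 (4.17%) met green H3K9ac regions, 46.8-fold, and 250 (3.65%) met red ones, 37.8-fold. Each of these excesses passed the circular-shift permutation test (adjusted p = 0.003). Over local shifts they were 25.6-fold, 16.9-fold, 25.0-fold and 14.4-fold, in the same order. Of 1393 H3K4me3 regions that met H3K9ac of 1 colour, 717 (51.5%) had the same colour in both marks, an odds ratio of 1.05 (0.84 to 1.30; Fisher's exact test, p = 0.70).

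H3K27me3 and H3K9ac regions rarely met. Red H3K27me3 regions met green H3K9ac regions 24 times, 2.78-fold over the shifts (circular-shift permutation test, adjusted p = 0.003), and red H3K9ac regions 2 times, where the central 95% of the shifts ran from 4 to 17 (adjusted p = 0.022 in the same permutation test). Green H3K27me3 regions met green H3K9ac regions 1 time (adjusted p = 0.068 in that permutation test) and red ones 0 times of 6574, against a shift mean of 6.90 (adjusted p = 0.00799, same permutation test). The first passed against local shifts, at 0.13-fold. The depletions in red H3K9ac did not pass among regions at or above the median width, nor with 50% of a region covered. Only 27 H3K27me3 regions met H3K9ac at all. Because green H3K27me3 met red H3K9ac 0 times, a small constant was added to every count before the odds ratio was taken. The odds ratio for sharing the colour, 0.31, had an interval of 0.0097 to 9.69 (Fisher's exact test, p = 1.0). Its side of 1 comes from that constant and gives no direction.

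Notch1 peaks in T-ALL were concentrated in red regions of H3K27me3 and H3K4me3. The 14569 peaks had a median width of 675 bp, and the broadest, 3850 bp, lay on chromosome 18 from 81167651 to 81171500 with 2 red H3K27me3 regions and 1 red H3K4me3 region. Of all peaks 3294 (22.6%, 21.9 to 23.3) shared bases with a red H3K27me3 region, 24.4-fold over circular shifts, and 1933 (13.3%, 12.7 to 13.8) with a red H3K4me3 region, 19.2-fold. Both passed the circular-shift permutation test (adjusted p = 0.00599) and were 6.57-fold and 6.06-fold over local shifts, and 37.0-fold and 32.3-fold with 50% of a peak covered. There were 556 peaks in red regions of both marks, against 437.0 if the 2 classes were independent among peaks (odds ratio 1.46, 1.31 to 1.62). No listed region of the 3 marks met 9770 of the peaks (67.1%).

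Notch1 peaks met green regions at about the chance level of whole-chromosome shifts. There were 102 peaks in green H3K27me3 regions (1.17-fold; circular-shift permutation test, adjusted p = 0.35) and 98 in green H3K4me3 regions (1.04-fold; same permutation test, adjusted p = 0.77). Against local shifts these counts were 0.40-fold and 0.50-fold, below chance in the local-shift permutation test, and with 50% of a peak covered they were 0.32-fold and 0.31-fold. Among regions and peaks at or above the median width, green H3K27me3 instead held an excess, at 1.68-fold. H3K9ac met 18 peaks in green and 20 in red regions, 2.17-fold and 2.19-fold over circular shifts (permutation test, adjusted p = 0.016 and 0.024). Neither passed against local shifts, among regions and peaks at or above the median width, or with only the peaks so limited.

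The colours differed in Notch1 binding for 2 of the 3 marks. A Notch1 peak was present in 24.7% of red and 1.12% of green H3K27me3 regions, an odds ratio of 29.0 (23.9 to 35.2). It was present in 17.2% of red and 1.02% of green H3K4me3 regions, an odds ratio of 20.1 (16.5 to 24.6). With 50% of a region covered these odds ratios were 164.8 and 154.9, and with Notch1 peaks at or above their median width that of H3K4me3 was 30.4. Both differences passed the rotation permutation test (p = 0.001, the smallest the rotations can give). For H3K9ac the shares were 2.27% of red and 1.89% of green regions, an odds ratio of 1.20 (0.64 to 2.27; Fisher's exact test, p = 0.63). Red H3K27me3 regions with a peak were wider, with a median of 950 bp against 700 bp for those without.

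**Figure D2:**
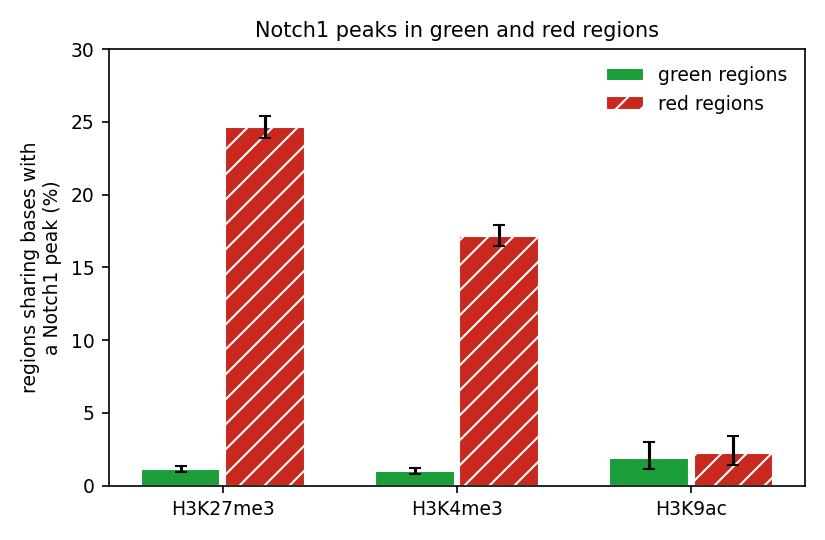
Percentage of green and red (hatched) regions of each mark that share at least 1 base with a T-ALL Notch1 peak; bars start at 0 and error bars are 95% Clopper-Pearson intervals, which cover counting error only. The red bars stand at 24.7% for H3K27me3 and 17.2% for H3K4me3, against about 1% for green, and the H3K9ac bars differ little.

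The deposited files all open on the same display window, chromosome 16 from 30061173 to 30072152. The 5 H3K27me3 regions in it were all red and covered 5700 bp. The largest, from 30064901 to 30067650, contained a Notch1 peak from 30066276 to 30066775. For H3K4me3, 3 regions were green and 1, from 30064001 to 30064850, was red. Both H3K9ac regions were green, and the Notch1 peak shared bases with the second, from 30066326 to 30067125. The peak also shared bases with the green H3K4me3 regions from 30065251 to 30066300 and from 30066451 to 30066950, and not with the red one. With 1 window, no test applies.

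**Figure D3:**
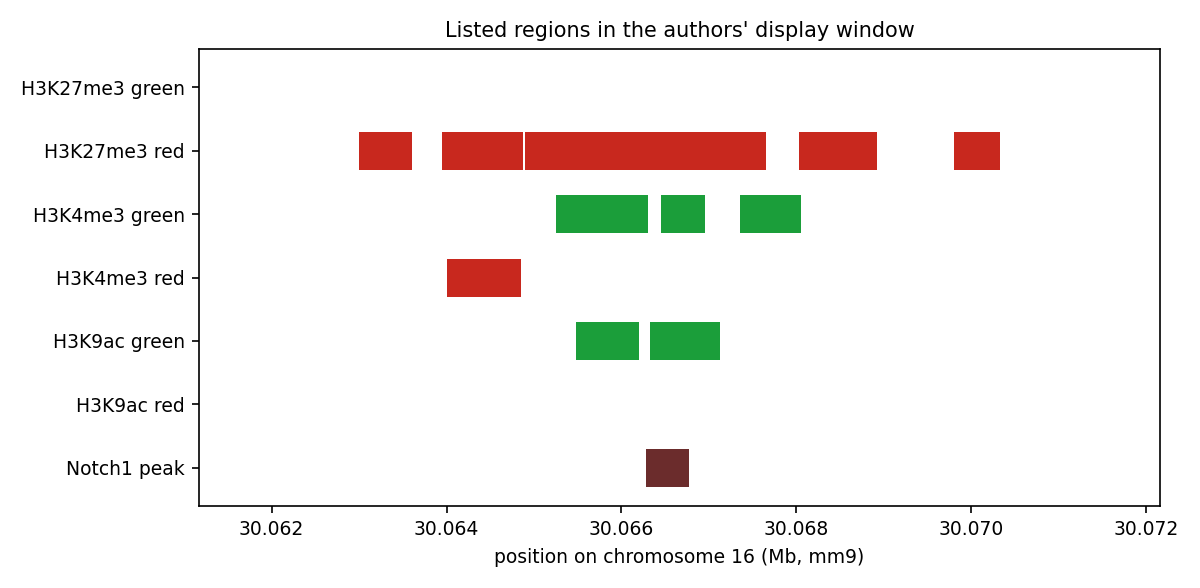
Map of all listed regions in the display window on chromosome 16 (x axis, position in Mb on mm9; each row is 1 list and each box 1 region drawn to scale, in its deposited colour for the histone marks and brown for Notch1). The 5 H3K27me3 boxes are red, 5 of the 6 H3K4me3 and H3K9ac boxes are green, and the Notch1 peak lies within the largest H3K27me3 box.

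The sex chromosomes, compared after their values were seen, departed from the autosomes. X held few listed regions for its span of 160.8 Mb, so its shares rest on a sparse part of the lists. By comparison chromosome 19, spanning 58.1 Mb, held 556 green and 459 red H3K27me3 regions. It also held 344 green and 367 red H3K4me3 regions. On X, 100 H3K27me3 regions were red and 3 were green, a green share of 2.91% (0.60 to 8.28), against 42.8% green on the autosomes (odds ratio 0.040; Fisher's exact test, adjusted p = 3.73e-20). That odds ratio was 0.023 among regions at or above the median width and 0.072 with clusters within 100 kb counted once. H3K4me3 regions on X were green in 134 cases and red in 82, a green share of 62.0% (55.2 to 68.5), against 47.6% on the autosomes (odds ratio 1.80, 1.37 to 2.37). This odds ratio was 1.43 among regions at or above the median width and 1.52 with clusters within 100 kb counted once. It was 2.16 with regions within 1 kb merged. On Y, 56 H3K4me3 regions were green and 3 red, a green share of 94.9% (85.9 to 98.9; odds ratio 20.6; Fisher's exact test, adjusted p = 8.72e-15). Counted as clusters within 100 kb, Y held 6 green and 1 red, and that difference did not pass Fisher's exact test. The Notch1 list held 28 peaks on X and 0 on Y.

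Among the autosomes the green share of H3K27me3 ran from 31.7% on chromosome 8 to 54.8% on chromosome 19. That of H3K4me3 ran from 41.2% on chromosome 18 to 58.4% on chromosome 3, and that of H3K9ac from 28.7% on chromosome 19 to 64.3% on chromosome 3.

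**Figure D4:**
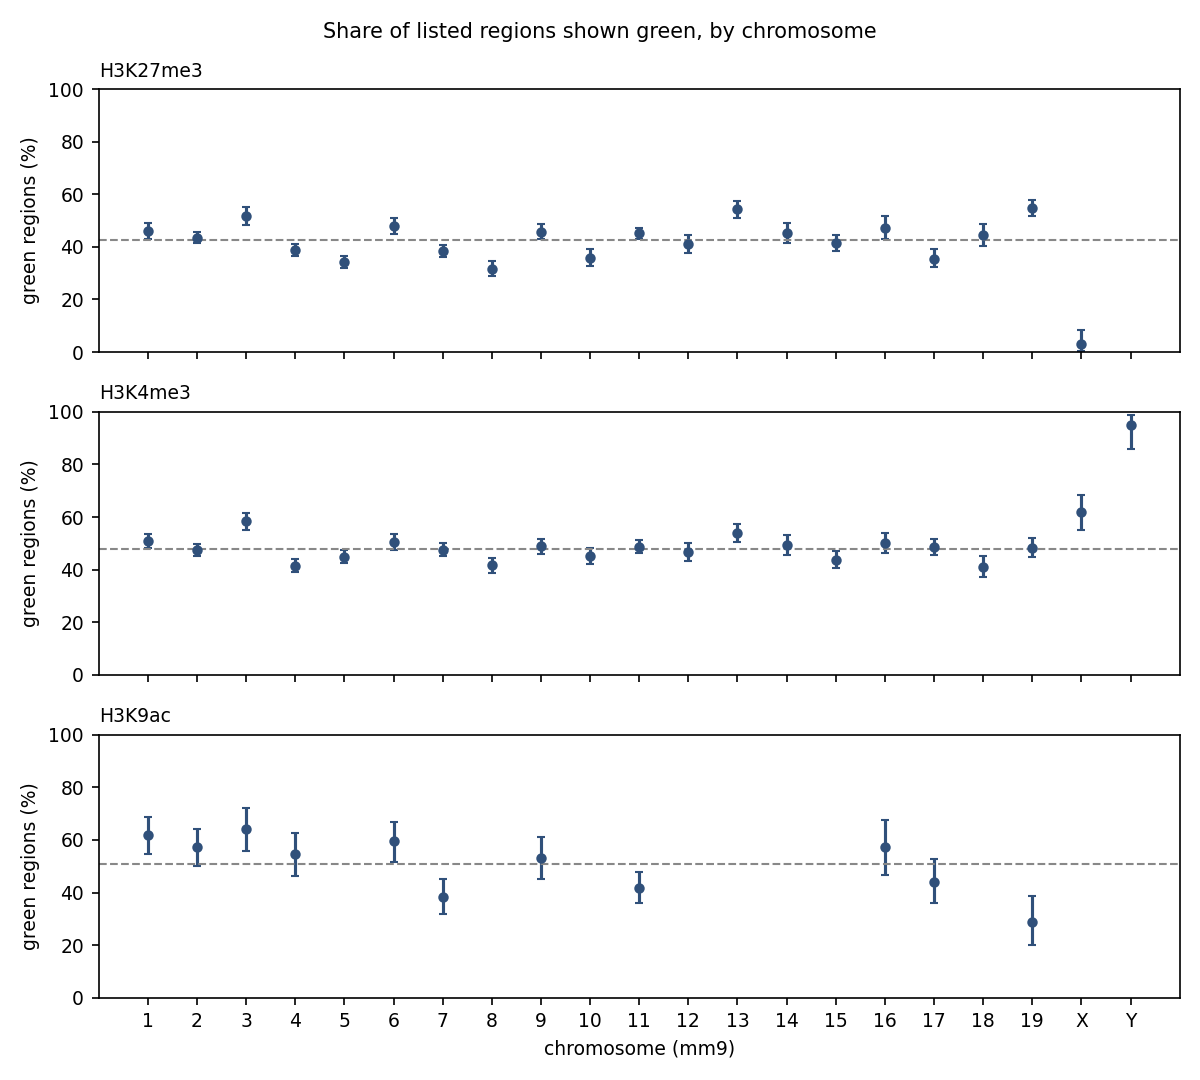
Percentage of the listed regions of each mark shown green, by mm9 chromosome; points are the shares, error bars 95% Clopper-Pearson intervals and the dashed line the share over all chromosomes of that mark. X stands at 2.91% for H3K27me3 and Y at 94.9% for H3K4me3, outside the 31.7% to 58.4% of the autosomes for these marks.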

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

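Local shifts, rotated colours, regions of 500 to 1000 bp, the 11-chromosome set and counting clusters once were chosen after seeing the data, and the other settings before the data were examined. No paired analysis was possible because the lists hold no values per library, and for the same reason no replicate could be left out. Alternatives that need genes, promoters or sequence were not run. Of 156 alternatives tried on 27 tested results, 133 kept the side of the threshold, and those called also kept direction. Values not called in either setting could cross 1. The odds ratio of a Notch1 peak in red against green H3K9ac regions went from 1.20 to 0.77 with 50% of a region covered. Some alternatives could not change a value: the H3K9ac list has no sex chromosomes, and rotation keeps the odds ratio. The excess of Notch1 in red regions ranged from 6.57-fold to 37.0-fold for H3K27me3 and from 6.06-fold to 32.3-fold for H3K4me3, and red H3K27me3 with red H3K4me3 from 5.03-fold to 24.5-fold. The odds ratio of a Notch1 peak in red against green regions ranged from 22.3 to 164.8 for H3K27me3 and from 16.8 to 154.9 for H3K4me3. Keeping regions at or above the median width left 5057 green and 6662 red H3K27me3, 5365 and 5792 H3K4me3, 482 and 473 H3K9ac regions and 7497 Notch1 peaks, by construction. It raised Notch1 in green H3K27me3 to 1.68-fold (called) and lowered Notch1 in green and red H3K9ac to 1.12-fold and 1.32-fold, both lost. It took the odds ratio of the H3K27me3 and H3K4me3 colours to 1.59, also lost. Notch1 peaks at or above their median width alone gave 1.07-fold and 1.57-fold for green and red H3K9ac, both lost. With 50% of a region covered, Notch1 in green H3K27me3 and green H3K4me3 turned to 0.32-fold and 0.31-fold (called), green H3K27me3 with red H3K4me3 fell to 1.10-fold and red H3K27me3 with green H3K4me3 to 1.26-fold. Both the median width and 50% coverage gave 0 regions for red H3K9ac with either colour of H3K27me3, no longer called. Local shifts turned Notch1 in green H3K27me3 and H3K4me3 to 0.40-fold and 0.50-fold, green H3K27me3 with green H3K4me3 to 0.62-fold (called) and Notch1 in red H3K9ac to 0.82-fold (not called). They took green H3K27me3 with red H3K4me3 to 1.04-fold, red with green to 1.17-fold and Notch1 in green H3K9ac to 1.27-fold, all lost, and called green H3K27me3 with green H3K9ac at 0.13-fold. Clusters on Y counted once gave an odds ratio of 6.61, lost with 6 green and 1 red clusters. Apart from the changes by construction, the causes were not tested. Depth is unknown, so what it limits cannot be stated.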

Other observations

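The tests of neighbouring colours, of relations across chromosomes and of the explanations weighed here were chosen after the results were seen. Red and green regions of one mark often lay side by side. Of 11160 red H3K4me3 regions 1518 (13.6%) had a green H3K4me3 region within 500 bp, 6.44-fold over local shifts (permutation test, p = 0.002), and of 13012 red H3K27me3 regions 1840 (14.1%) had a green neighbour, 2.89-fold (same permutation test, p = 0.002). For H3K9ac it was 19 of 926 (2.05%), 4.71-fold (same permutation test, p = 0.002).

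Some places stood apart from the rest. On chromosome 1 from 90134501 to 90167150, 17 red H3K4me3 regions formed the largest red cluster of that mark, together with 12 red H3K27me3 regions. Near the end of X, from 166409551 to 166440925, 12 red H3K4me3 regions lay with 9 red H3K27me3 regions. The largest green H3K4me3 cluster, 18 regions on chromosome 3 from 25417876 to 25453150, held 0 Notch1 peaks and 0 H3K9ac regions. The largest Notch1 cluster, 12 peaks on chromosome 2 from 179911126 to 179940675, held 4 red H3K27me3 and 6 red H3K4me3 regions and 0 green regions.

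The concentration of T-ALL Notch1 peaks in red regions of both a repressive and an activating mark was weighed first. Crowding of all lists into the same long stretches of the chromosomes may account for part of the excess, since local shifts lowered it. It does not account for all, since 6.57-fold remained for H3K27me3 and 6.06-fold for H3K4me3. The local shifts moved peaks by at least 10 kb, so they cannot test crowding into shorter stretches, which remains open. Width did not remove the excess either, since the lower odds ratio of the 2 marks among regions of 500 to 1000 bp was 21.8. A shortage of reads at Notch1 peaks shared by the libraries of every mark could make red H3K9ac regions rich in Notch1 peaks. That holds only if the colours mean the same in every list, which the headers do not state. The odds ratio there was 1.20 with an upper bound of 2.27. It rests on 21 red and 18 green H3K9ac regions with a peak, and few peaks met that list, so it cannot decide the question. A cause shared by all marks, at Notch1 peaks or over wider stretches, remains open. The red share of H3K9ac rose with Notch1 density across 11 autosomes (r = 0.76), which does not tell causes apart. A shortage limited to the H3K4me3 and H3K27me3 libraries and a difference in base composition also remain open. So does a change of both marks at Notch1-bound sites in T-ALL, as no sequence or read count was used here.

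H3K4me3 was shifted to green on both Y (94.9%) and X (62.0%), while H3K27me3 on X was mostly red (2.91% green). Unequal sex of the DP and T-ALL animals, which the labels do not give, may underlie the H3K27me3 on X and the H3K4me3 on Y, but these values raised that hypothesis and so do not test it, and it remains open. A difference in reads from the whole of X would move both marks on X to the same colour if the colours mean the same in both lists, which the headers do not state, and the odds ratios of green went apart, at 1.80 (1.37 to 2.37) for H3K4me3 and 0.040 (0.013 to 0.126) for H3K27me3. The H3K4me3 value on X ran from 1.43 to 2.16 over the alternatives, and these intervals take clustered regions as independent. Within 100 kb the Y regions form 6 green clusters and 1 red one, so their number overstates the evidence. A change of H3K27me3 on X in T-ALL itself was not tested.

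Which colour is higher in T-ALL may be read from the display window, as a hypothesis. General knowledge of mm9, not an annotation used here, places Hes1, a classical Notch target gene, in that window. If green is higher in T-ALL, a Notch1-bound and active Hes1 would have red H3K27me3 and green activating marks, and 100% of the 5 H3K27me3 regions were red and 5 of the 6 H3K4me3 and H3K9ac regions green. Across the lists, 3294 Notch1 peaks met red and 102 met green H3K27me3 regions, the same side as the window. For H3K4me3, 1933 peaks met red regions (19.2-fold over circular shifts) and 98 met green ones (1.04-fold), the other side from the window. On that reading, most Notch1 peaks that met H3K4me3 would lie where this activating mark was lower in T-ALL. A single locus with an unchecked placement cannot decide which colour is higher.

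Red shares also tended to rise with Notch1 density from autosome to autosome, with exceptions. Chromosome 19 had the lowest red share of H3K27me3 among the autosomes, 45.2%, at 80.9 Notch1 peaks per 10 Mb. X did not follow the tendency for H3K27me3, with 100 red and 3 green regions at 1.74 Notch1 peaks per 10 Mb. Over 19 autosomes the red share of H3K27me3 rose with Notch1 peaks per 10 Mb (Pearson r = 0.51, permutation p = 0.026, adjusted 0.026; Spearman rho = 0.63, permutation p = 0.0045, adjusted 0.0059), with r = 0.56 without chromosomes 3 and 11. For H3K4me3 the values were r = 0.52 (permutation p = 0.021, adjusted 0.026) and rho = 0.60 (permutation p = 0.0078, adjusted 0.0078), with r = 0.53 without the same chromosomes. For H3K9ac over 11 chromosomes they were r = 0.76 (permutation p = 0.0066, adjusted 0.013) and rho = 0.81 (permutation p = 0.0041, adjusted 0.0059), with r = 0.71 without them. The red shares of H3K27me3 and H3K4me3 rose together (r = 0.68, permutation p = 0.0013, adjusted 0.0051; rho = 0.73, permutation p = 0.00048, adjusted 0.0019), with r = 0.70 without chromosomes 8 and 19. These relations, adjusted as 1 family, are across chromosomes, which are not replicate samples. Among the autosomes Notch1 density ran from 28.0 peaks per 10 Mb on chromosome 3 to 104.3 on chromosome 11.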
